A study of Mus musculus with 5 samples.

How the data were processed

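Tfr cells sorted as live CD4 T cells with Foxp3, CXCR5, PD-1 and ICOS were profiled by RNA-seq, in 3 WT and 2 Cebpa_KO libraries from spleen, 21 days after imiquimod. Per the labels' protocols, cDNA was made with a low-input full-length kit and tagmented. The labels describe each library as a pool of several mice, so p-values measure the spread between pools.

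The submitters' processing notes name STAR 2.7.11b, StringTie 2.1.3b and the mouse build mm39. The annotation release, read length and strand setting are not given in the sources used here, so reads of overlapping antisense genes such as Xist and Tsix cannot be told apart. Per the file headers, each library has a gene abundance table with coverage, FPKM and TPM. The TPM values deposited by the authors are treated as a score, since the column holds every signal in 2 forms: loci assembled in that library, which sum to 1000000, and annotated genes, which repeat 96.7% to 97.6% of it. The annotated gene rows were used. FPKM and coverage, deposited by the authors as a signal per base, served only for the depth, which is their ratio and came to 6.76 to 7.08 gigabases aligned per library. No read counts are in these tables, so count models, counting intervals and detection floors were not used.

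TPM rows of 1 gene ID were summed, and each library was divided by its median ratio to the geometric mean of genes with a TPM of at least 1 in all libraries. The factors were 0.994, 1.04 and 0.984 for WT and 0.998 and 1.01 for Cebpa_KO. Genes with a TPM of at least 1 in at least 2 of 5 libraries, 16254 in all, were tested on log2(scaled TPM + 1). A fold change on that scale understates the change of low genes. The test was limma 3.58.1 in R 4.3.3 with an intensity trend and Benjamini-Hochberg adjustment, at a threshold of 0.05. Cebpa also had an exact permutation test. Gene types came from GENCODE M21, which matched 51880 of 57186 gene IDs and was not used for coordinates, since it is on another build. Coordinates are those of the deposited tables.

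The design, the alternatives, the rule for named genes and 31 gene lists were fixed before the data were examined. The rule names Cebpa, 14 key genes, up to 4 members of each list with the smallest p, and the 10 largest rises and falls past the threshold whose groups did not overlap and whose higher group had a mean of at least 5. Left out of the last part were 426 gene models, 70 pseudogenes and 37 receptor or antibody segments among 2785 genes that met its conditions. Some genes that the rule takes are not reported here. Genes named outside the rule, such as Hspa1a, Fos, Jun, Jchain, Igkc, Tigit, Tnfrsf4 and Nrp1, were chosen after their values were seen. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The estimated form rests on 3 residual degrees of freedom and has little power. A list that fails it is left undecided.

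On simulated data for the comparison of Cebpa_KO with WT, with 15676 genes, the fit called 59 of 100 genes changed by 1 and 81 of 100 changed by 2 on the log2 scale, and 12 unchanged genes. Genes varied independently of each other there, so calls that arise from variation shared between genes were not simulated. The changed genes were drawn only from genes well above the filter, so these shares do not cover low genes. They were also a smaller share of all genes than the data called, and the adjustment depends on that share. The alternatives were other pseudocounts of 0.1 and 5, no filter, a filter at a TPM of 5, unscaled TPM, quantile normalization, array weights, no trend, robust estimation, each library left out and a replicate block. WT replicate 3 set alone against both Cebpa_KO libraries, the assembled loci and the counts without chromosomes X and Y were added after seeing the data. Fits without a library, or with WT replicate 3 as the only WT library, filter and scale again, whereas medians given against WT replicates 1 and 2 or against WT replicate 3 keep the 16254 genes and the scaling of all 5 libraries. A covariate that grouped libraries by their Hspa1a level was also fitted after seeing the data. It is not reported, because it defines groups by a measured outcome. Ratios of the difference to WT replicate 3 over that to WT replicates 1 and 2, tested after seeing the data as a sign of handling, are not reported either, because they share libraries with each other and with the choice of genes. Tables were read with pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9.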

Results

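RNA was sequenced from follicular regulatory T (Tfr) cells, the Foxp3-expressing CD4 T cells that enter B cell follicles and restrain germinal centre responses. The cells were sorted from mouse spleen 21 days after treatment with imiquimod, an agonist of the RNA sensor TLR7. The WT group held 3 libraries and the Cebpa_KO group held 2. In Cebpa_KO mice a Cre recombinase expressed from Foxp3 deletes floxed Cebpa, the gene of the transcription factor C/EBP alpha, in regulatory T cells. The WT mice carried a green fluorescent reporter of Foxp3 instead, so the groups differed in their Foxp3 allele as well as in Cebpa. Each library pooled sorted cells of several mice. Aligned depth was 6.83, 7.08 and 6.77 gigabases in WT replicates 1, 2 and 3, and 6.80 and 6.76 gigabases in Cebpa_KO replicates 1 and 2. Between 15250 and 15691 genes per library had a TPM of at least 1. Values below are scaled TPM with the SD over libraries, n = 3 for WT and n = 2 for Cebpa_KO.

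The comparison asked how Tfr cells differ when they lack C/EBP alpha, in a study that places this factor downstream of the cytokine IL-6. Cebpa itself (ENSMUSG00000034957, mm39 chromosome 7, 34818718 to 34821353) was at 12.9, 17.7 and 12.8 in the WT libraries. It was at 0.317 and 0.550 in the Cebpa_KO libraries, a mean 33.4 times lower. The log2 fold change was -3.42 with a standard error of 0.20 (limma, adjusted p = 0.00371). Without Cebpa_KO replicate 2 the value was -3.54 and the adjusted p 0.0512, and over all alternatives the adjusted p lay between 0.00163 and 0.0512. The exact permutation test of the 5 libraries, two-sided, gave p = 0.1, the smallest that 10 splits allow.

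Foxp3, the lineage factor of regulatory T cells, was lower in Cebpa_KO, although the cells had been sorted as Foxp3-positive. Foxp3 (ENSMUSG00000039521, chromosome X, 7439883 to 7461484) stood at 98.3 ± 13.4 in WT and 6.16 ± 0.821 in Cebpa_KO, 16.0 times lower (log2 fold change -3.79, standard error 0.15, limma adjusted p = 0.00115). Il1rn, the IL-1 receptor antagonist, fell from 49.9 ± 4.68 to 3.94 ± 0.115. Lrrc32, which displays latent TGF-beta on regulatory T cells, fell from 100.2 ± 6.34 to 22.1 ± 2.09. In the other direction, Il21, the cytokine by which follicular helper cells drive B cells, rose from 12.7 ± 2.14 to 53.3 ± 4.06. Tnfsf8, the ligand of CD30, rose from 21.3 ± 1.99 to 105.6 ± 10.6.

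**Figure D1:**
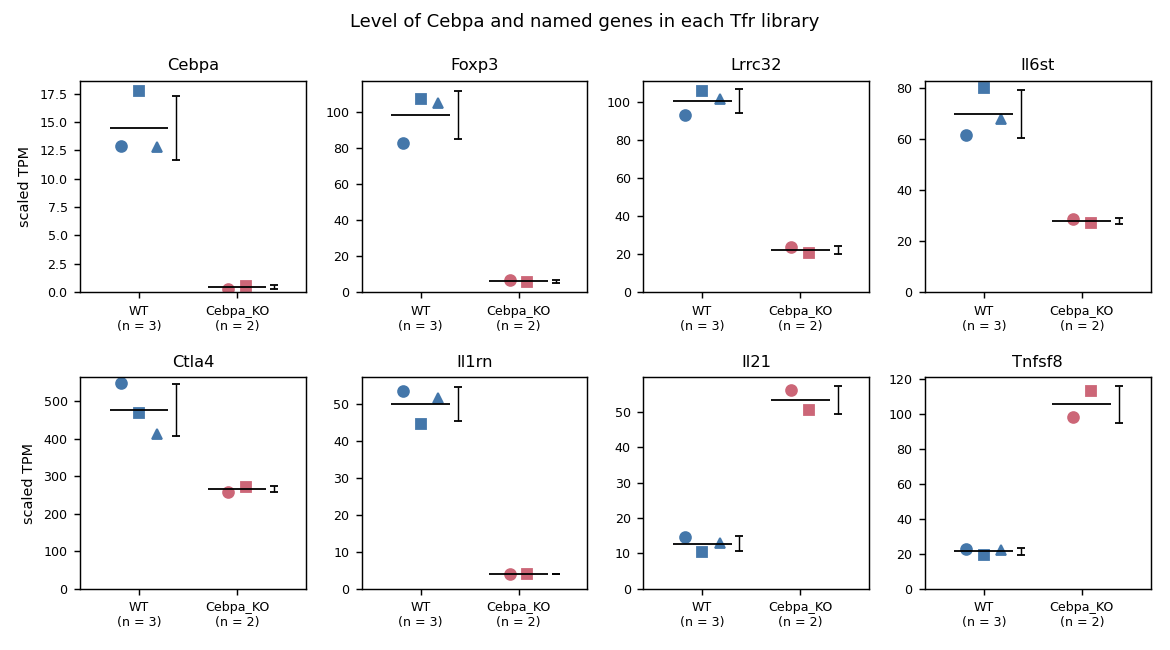
Scaled TPM of 8 genes on linear axes, with circles, squares and triangles for replicates 1, 2 and 3, a line for the group mean and a bar for 1 SD. Cebpa, Foxp3, Lrrc32, Il6st, Ctla4 and Il1rn were lower in both Cebpa_KO libraries than in all 3 WT libraries, and Il21 and Tnfsf8 were higher.

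Of 16254 genes tested, 1614 were higher and 1596 lower in Cebpa_KO (limma, Benjamini-Hochberg adjusted p under 0.05), of which 368 and 401 differed by at least 2-fold on the log2(scaled TPM + 1) scale. The count rested on both Cebpa_KO libraries. With Cebpa_KO replicate 1 left out, 9 genes were higher and 25 lower. With Cebpa_KO replicate 2 left out, 5 were higher and 18 lower, although 3571 and 3777 genes then had an unadjusted p under 0.05. Leaving out WT replicate 1 gave 966 higher and 1013 lower, and leaving out WT replicate 2 gave 437 and 390. Foxp3, Il1rn, Lrrc32, Cxcr4, Ctse and Sostdc1 passed in each of these fits, whereas 79 and 83 named genes that had passed no longer did without Cebpa_KO replicate 1 or 2. The groups did not overlap in 9213 genes, 56.7% of those tested, where chance gives 20%.

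**Figure D2:**
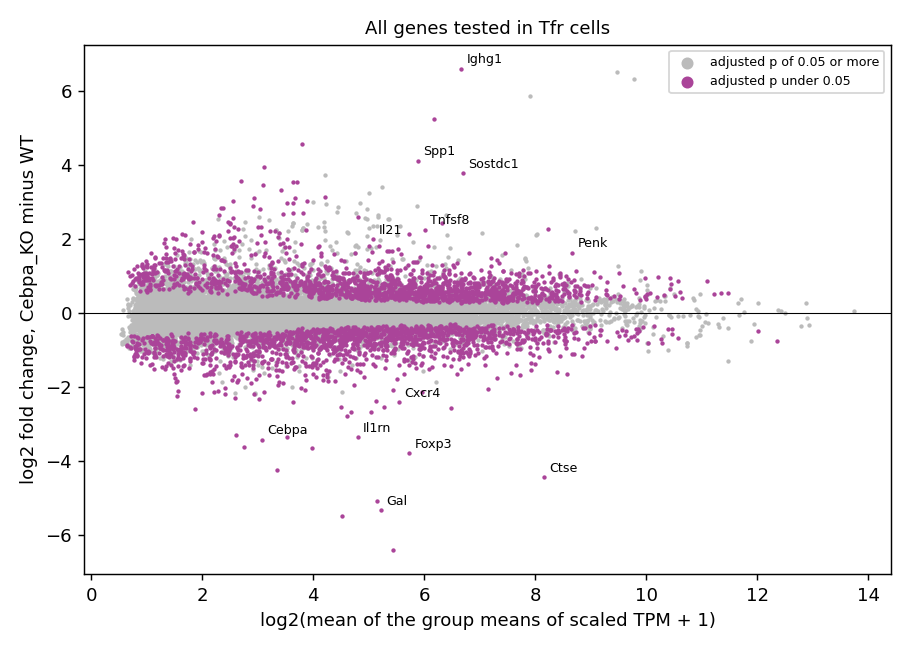
Log2 fold change of every tested gene, Cebpa_KO minus WT, against the log2 of its mean scaled TPM plus 1, with 1 point per gene and genes past an adjusted p of 0.05 in purple. Foxp3 at -3.79 and Ctse at -4.43 lie below the bulk of the genes, and Ighg1 at 6.62 lies above it.

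The 10 largest falls included 4 genes of the Y chromosome, Eif2s3y, Ddx3y, Uty and Kdm5d, which summed to 162, 160 and 151 in WT and to 0 and 0.0311 in Cebpa_KO. Xist, the RNA that silences an X chromosome in females, stood at 11.4 and 10.7 in Cebpa_KO and at 0.0220 or less in WT. Tsix, which overlaps Xist on the other strand, was called higher by 3.97 on the log2 scale, but the reads of the pair cannot be told apart. The sex of the mice therefore followed the genotype in all 5 libraries. Among the other large falls, Gal, the neuropeptide galanin, went from 72.1 ± 25.8 to 0.795 ± 0.682. Ctse, the aspartic protease cathepsin E, went from 544.5 ± 50 to 26.3 ± 14.8. Of the largest rises, Spp1, which encodes osteopontin, went from 6.0 ± 4.26 to 110.7 ± 36.0. Sostdc1, a secreted BMP and Wnt antagonist, went from 13.2 ± 3.21 to 192.1 ± 16.4. Npnt, an integrin ligand of the extracellular matrix, Lad1, Cd109 and the chemokine Ccl1 rose by 3.34, 3.56, 3.04 and 3.13 on the log2 scale. Erdr1x rose by 3.14, but it has a near copy on the Y chromosome and its reads cannot be placed with certainty. Ighg1, the IgG1 heavy chain, was the largest rise, at 0.254, 0.205 and 3.09 in WT and 288 and 111 in Cebpa_KO.

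The Treg core list moved down in part. Of its 20 members 7 fell and 1 rose, and 9 fell and 1 rose when adjusted over the list alone. The 19 members other than Foxp3 had a median log2 fold change of -0.33, near the -0.29 of 15 general T cell identity genes. The fall of the list as a whole was thus not shown to be particular to regulatory T cell genes. Besides Foxp3 and Lrrc32, Nt5e, the ecto-enzyme CD73, fell by 0.80 on the log2 scale, and Ctla4, an inhibitory receptor, fell from 476.4 ± 68.4 to 264.3 ± 8.03. Il2ra, the IL-2 receptor alpha chain, fell by 0.54. Penk, which encodes enkephalin, rose from 197.9 ± 42.6 to 615.3 ± 151. Tigit, Tnfrsf4 and Nrp1 had log2 differences of 0.12, 0.12 and 0.16 and did not pass. The list was lower by camera (adjusted p = 0.00648), with an adjusted p = 0.60 with an estimated correlation, 0.0977 without Cebpa_KO replicate 1 and 0.0699 in the assembled loci. Of the 20 effector Treg and suppression genes, Il1rn and Tnfrsf1b, a TNF receptor, fell and Ccr8, a chemokine receptor of activated regulatory T cells, rose by 1.04, the same counts as when adjusted over the list alone. Il10 was at 12.3, 11.3 and 34.4 in WT and at 37.3 and 41.5 in Cebpa_KO, which did not pass (adjusted p = 0.143, limma), nor did Prdm1, and the list as a whole did not pass (adjusted p = 0.240). Both depended on WT replicate 3: without it Il10 rose by 1.66 on the log2 scale (limma, adjusted p = 0.00507; 0.0285 with array weights), and 8 genes of the list rose and 2 fell (camera, adjusted p = 0.0292). In the assembled loci the list had an adjusted p = 0.0486.

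Genes of the follicular and germinal centre programme went both ways. Of 20 members 6 fell and 2 rose, in the test over all genes and when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.275). Bcl6, the transcriptional repressor that directs follicular T cells, fell by 0.85, Cxcr5, the receptor that draws cells into follicles, by 0.78 and Icos, a costimulatory receptor, by 0.71 on the log2 scale. Id3, an inhibitor of E proteins, fell from 282.8 ± 19.0 to 92.4 ± 15.6, and Sh2d1a, the adaptor SAP, fell by 0.79. The rises were Il21 and Tnfsf8. Pdcd1, which encodes PD-1 and was part of the sort, was at 762, 682 and 720 in WT and 633 and 663 in Cebpa_KO and did not pass (limma, adjusted p = 0.25).

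Both chains of the IL-6 receptor were lower in Cebpa_KO. Il6st, the shared signalling chain gp130, fell from 69.8 ± 9.39 to 27.8 ± 1.06, and Il6ra, the IL-6 binding chain, from 16.6 ± 5.48 to 5.63 ± 0.00592. Il6ra passed with an adjusted p = 0.0344 (limma) but did not against WT replicates 1 and 2, at 0.0563. In the list of 18 IL-6 and STAT3 genes 3 fell and 4 rose, also when adjusted over the list alone. The falls were completed by Hif1a, and the rises included Socs1, a feedback inhibitor of cytokine signalling, by 0.81 and Bcl3 by 0.86. Leaving out WT replicate 3 gave 2 falls and 6 rises. The list as a whole did not pass (camera, adjusted p = 0.982). Among 6 C/EBP family genes tested, Cebpa and Ddit3 fell and Cebpg and Cebpd rose, by 0.76 and 0.63. Cebpg and Cebpd code for related basic leucine zipper factors, and Cebpg lies close to Cebpa, at 34745847 to 34755998 on chromosome 7. Ddit3 and Cebpd (limma, adjusted p = 0.0351 and 0.0402) did not pass against WT replicates 1 and 2, at 0.0558 and 0.0592. Adjusted over the list alone 2 fell and 3 rose. The median of that list was 0.26, its mean -0.37 and its camera direction upward (adjusted p = 0.828). Cebpb was at 63.4, 55.8 and 124 in WT and at 84.6 and 93.3 in Cebpa_KO and did not pass (limma, adjusted p = 0.669), with a log2 difference of 0.22 against all WT libraries and -0.48 against WT replicate 3 alone. The difference was 0.57 without WT replicate 3 (adjusted p = 0.0231). Of 13 myeloid targets of C/EBP alpha 1 fell, Il6ra, and none rose, with 2 falls and 1 rise when adjusted over the list alone (camera, adjusted p = 0.226, and 0.00227 upward without Cebpa_KO replicate 2). Leaving out WT replicate 3 gave 4 rises and no fall. The myeloid target list names S100a8, S100a9, Csf3r and Ltf, as the neutrophil list does. Mpo stood at 3.34, 1.77 and 6.12 in WT and at 50.8 and 10.6 in Cebpa_KO. Prtn3 stood at 0.320, 0.977 and 1.82 in WT and at 16.6 and 4.08 in Cebpa_KO. Rises in this list were not told apart from RNA of other cells in the pools.

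Genes of resting T cells were lower. Of 15 naive and resting genes 6 fell and none rose, 9 when adjusted over the list alone. Foxo1, a transcription factor of quiescence, fell by 0.95, and Rgs10 and Dapl1 fell by 1.41 and 1.87. The list was lower by camera (adjusted p = 0.000493), with an adjusted p = 0.636 with an estimated correlation. Trafficking genes were lower too, with 6 of 14 falling and none rising, also when adjusted over the list alone. Cxcr4, the receptor of the stromal chemokine CXCL12, fell from 77.3 ± 7.83 to 13.7 ± 1.51, and Selplg, a selectin ligand, S1pr4 and Itgb7 fell by 0.95, 0.94 and 0.75. That list had an adjusted p = 0.0200 by camera and an adjusted p = 0.60 with an estimated correlation. With WT replicate 3 as the only WT library it did not pass (adjusted p = 0.0584), and 2 genes fell and 1 rose. Of 15 T cell identity genes 5 fell, among them Cd5, Cd28, Cd3d and Trac, by 0.60, 0.80, 0.62 and 0.48, and 9 fell when adjusted over the list alone. Trac was not a stable call. It stood at -6.36 in the assembled loci and at -0.31 with quantile normalization (adjusted p = 0.283 and 0.117), and did not pass with no filter (0.18), with WT replicate 3 as the only WT library (0.0533) or when any library but WT replicate 3 was left out (0.0780 to 0.214). The adjusted p = 0.000493 by camera became an adjusted p = 0.636 with an estimated correlation.

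Interferon-stimulated genes were higher in Cebpa_KO. Of 25 members 11 rose and none fell, 14 when adjusted over the list alone (camera, adjusted p = 4.41e-05, with an adjusted p = 0.636 with an estimated correlation). Bst2, the antiviral protein tetherin, rose by 1.28, Isg15, a ubiquitin-like modifier, by 1.11, Oasl2 by 1.16 and Isg20 by 0.74, although Isg20 stood at -3.35 in the assembled loci. Of 15 Th1 and cytotoxic genes 2 rose, Tbx21, the lineage factor T-bet, by 1.43 and Il18r1 by 0.77, and the count was 2 when adjusted over the list alone. Ifng was at 3.02, 1.95 and 14.0 in WT and at 21.4 and 35.1 in Cebpa_KO and did not pass (log2 fold change 2.34, adjusted p = 0.0765), but did without WT replicate 3, at 3.05 (adjusted p = 0.00816), and with array weights, at 2.75 (adjusted p = 0.0179). Without WT replicate 3, 9 of the 15 rose, and with WT replicate 3 as the only WT library 1 rose and the list did not pass (camera, adjusted p = 0.541). That list had an adjusted p = 0.0110 by camera and an adjusted p = 0.636 with an estimated correlation, and its median was 1.10 against WT replicates 1 and 2 and 0.28 against WT replicate 3. In the Th17 list of 9 genes Ahr, a ligand-activated transcription factor, rose by 1.55 and Tmem176b fell, in both tests of single genes, over all genes and adjusted over the list alone. The Th17 list did not pass (camera, downward, adjusted p = 0.877), with a median of -0.14 and a mean of 0.10. Of 4 tested Th2 genes Ccr4 and Il4ra fell by 1.15 and 0.79, with 2 falls and 1 rise when adjusted over the list alone.

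Lists of glycolysis, ribosomal protein, oxidative phosphorylation, unfolded protein response and cholesterol synthesis genes were higher by camera with a preset correlation. Of 17 glycolysis genes 10 rose and 3 fell, also when adjusted over the list alone. Ldha, lactate dehydrogenase A, Tpi1 and Pgam1 rose by 0.78, 0.74 and 0.74, while the lactate exporter Slc16a3 fell by 0.60. Tpi1 stood at -1.13 in the assembled loci. The list had an adjusted p = 0.0110 by camera and an adjusted p = 0.60 with an estimated correlation. Of 37 ribosomal proteins 14 rose, and 23 when adjusted over the list alone, with Rps15 rising by 0.73 and Rpl27 by 0.65 (camera, adjusted p = 4.19e-07, with an adjusted p = 0.636 with an estimated correlation). In the list of 30 oxidative phosphorylation genes 6 rose, led by Cycs, cytochrome c, by 0.83, and 9 when adjusted over the list alone (camera, adjusted p = 0.000493, with an adjusted p = 0.636 with an estimated correlation). Of 22 genes of the unfolded protein response 6 rose, including the chaperones Sdf2l1 and Hsp90b1, and Ddit3 fell, with 8 rises and 3 falls when adjusted over the list alone (camera, adjusted p = 0.0357, with an adjusted p = 0.636 with an estimated correlation). That call ended without WT replicate 1, WT replicate 2 or Cebpa_KO replicate 1, at adjusted p of 0.0626, 0.0851 and 0.0892, and with quantile normalization, at 0.0539, while 11 rose and none fell without WT replicate 3. Of 20 cholesterol synthesis genes 5 rose, including Idi1 by 1.00 and Sqle by 0.88, and 10 when adjusted over the list alone (camera, adjusted p = 0.0110, with an adjusted p = 0.752 with an estimated correlation). Without WT replicate 3 the adjusted p of the cholesterol list was 0.0597 and its median 0.24, against 0.33 with all libraries. Myc, a driver of growth, and the cytokine gene Tnf rose by 0.91 and 0.60, whereas Cd5 and Egr2 fell. These were the 2 rises and 2 falls among 17 TCR-induced genes, with 2 rises and 3 falls when adjusted over the list alone, and the list did not pass (camera, adjusted p = 0.912). There were 6 rises and 3 falls without WT replicate 3. The pro-apoptotic Bbc3 and Bcl2l11 fell by 0.96 and 1.30, and none of 17 apoptosis regulators rose, also when adjusted over the list alone. That list did not pass (camera, adjusted p = 0.240).

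WT replicate 3 stood apart from WT replicates 1 and 2 in several lists. Hspa1a, an inducible heat shock protein, stood at 0.911 and 0.684 in WT replicates 1 and 2, at 690 in WT replicate 3 and at 1147 and 1238 in Cebpa_KO, and Fos and Jun went the same way. Hspa1a and Hspa1b are near-identical copies that share reads. Of 20 stress and immediate early genes 5 rose, including Hspd1, a mitochondrial chaperonin, by 1.15 and Atf3 by 2.86, and 7 when adjusted over the list alone (camera, adjusted p = 0.000498, with an adjusted p = 0.752 with an estimated correlation). The count was 17 without WT replicate 3. The median of the list was 1.53 against WT replicates 1 and 2 and 0.19 against WT replicate 3. Of 28 cell cycle genes 4 rose, the DNA replication helicase genes Mcm2, Mcm3, Mcm5 and Mcm6, and 6 when adjusted over the list alone (camera, adjusted p = 0.00178, with an adjusted p = 0.752 with an estimated correlation). Without WT replicate 3, 10 cell cycle genes rose and 1 fell, and with WT replicate 3 as the only WT library 27 of 28 rose. The cell cycle median was 0.15 against WT replicates 1 and 2 and 1.08 against WT replicate 3. None of 13 mitochondrially encoded genes passed, also when adjusted over the list alone. But 2 fell without WT replicate 1 or without WT replicate 3, and 12 fell with WT replicate 3 as the only WT library. Their median was -0.46 against WT replicates 1 and 2 and -1.26 against WT replicate 3. That list had an adjusted p = 0.00542 by camera and an adjusted p = 0.752 with an estimated correlation.

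**Figure D3:**
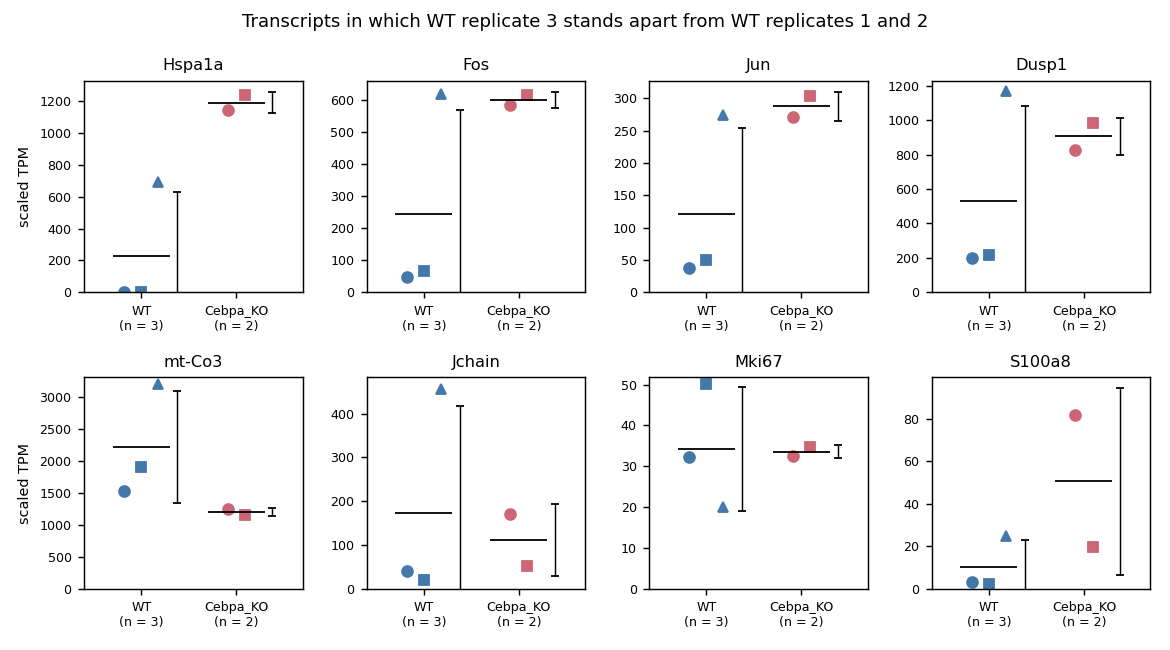
Scaled TPM of 8 transcripts on linear axes that start at 0, with circles, squares and triangles for replicates 1, 2 and 3, a line for the group mean and a bar for 1 SD that is not drawn below 0. Hspa1a stood at 690 in WT replicate 3 against 0.911 and 0.684 in WT replicates 1 and 2, and Jchain, an antibody joining chain, at 456 against 41.3 and 20.8.

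Markers of other cell types varied between libraries within each group. The neutrophil transcript S100a8 was at 3.34, 2.05 and 24.8 in WT and at 81.8 and 19.4 in Cebpa_KO, and none of 7 neutrophil markers passed, also when adjusted over the list alone (camera, adjusted p = 0.0479, with an adjusted p = 0.752 with an estimated correlation). The call was not stable: it ended without WT replicate 1, WT replicate 2 or Cebpa_KO replicate 1, at 0.159, 0.136 and 0.211, with pseudocounts of 0.1 and 5, at 0.0524 and 0.0534, with the filter at a TPM of 5, at 0.0676, and in the assembled loci, at 0.0757. Without WT replicate 3, 4 of the 7 rose, with a median of 3.07 (camera, adjusted p = 0.00517). The globin Hbb-bs was at 17.1, 9.98 and 121 in WT and at 383 and 42.4 in Cebpa_KO, and none of 9 erythroid and platelet markers passed, also when adjusted over the list alone (camera, adjusted p = 0.0599). That list passed without WT replicate 3, at 0.0235 and with 1 rise, without Cebpa_KO replicate 2, at 0.000818, and with no filter, quantile normalization or array weights, at 0.0341, 0.0451 and 0.0313. Of 16 B cell markers 1 fell, Cd22, an inhibitory receptor, from 63.0 ± 5.45 to 12.4 ± 10.9, a log2 fold change of -2.54 against -0.26 in the assembled loci (adjusted p = 0.0311 and 0.945), and 0 when adjusted over the list alone (camera, adjusted p = 0.395, and 0.00035 upward without Cebpa_KO replicate 2). Cd22 did not pass without WT replicate 1, WT replicate 2 or Cebpa_KO replicate 2 (adjusted p = 0.0773, 0.0952 and 0.0678), with no filter (0.133) or with WT replicate 3 as the only WT library (0.155). Of 11 plasma cell markers 1 rose, Ighg1, also when adjusted over the list alone (camera, adjusted p = 0.395). This too depended on WT replicate 3: without it 2 rose, with a median of 1.31 (camera, adjusted p = 0.00679), and with WT replicate 3 as the only WT library the median was -1.75. The light chain Igkc was at 1283, 749 and 9053 in WT and at 4394 and 1660 in Cebpa_KO. None of 12 monocyte and macrophage markers passed, also when adjusted over the list alone (camera, adjusted p = 0.877, and 0.0277 upward without Cebpa_KO replicate 2), and of 2 dendritic cell markers Bst2 rose in both. Of 7 CD8 T and NK cell markers 1 fell, Klrb1c, which encodes an NK cell receptor, by 1.66, against 0.071 in the assembled loci, and 3 when adjusted over the list alone (camera, adjusted p = 0.0167, with an adjusted p = 0.60 with an estimated correlation, 0.0701 without WT replicate 3 and 0.17 in the assembled loci). The 5 sex-linked genes, with 4 falls and 1 rise, also when adjusted over the list alone, passed by camera (adjusted p = 0.000726) and had an adjusted p = 0.60 with an estimated correlation.

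**Figure D4:**
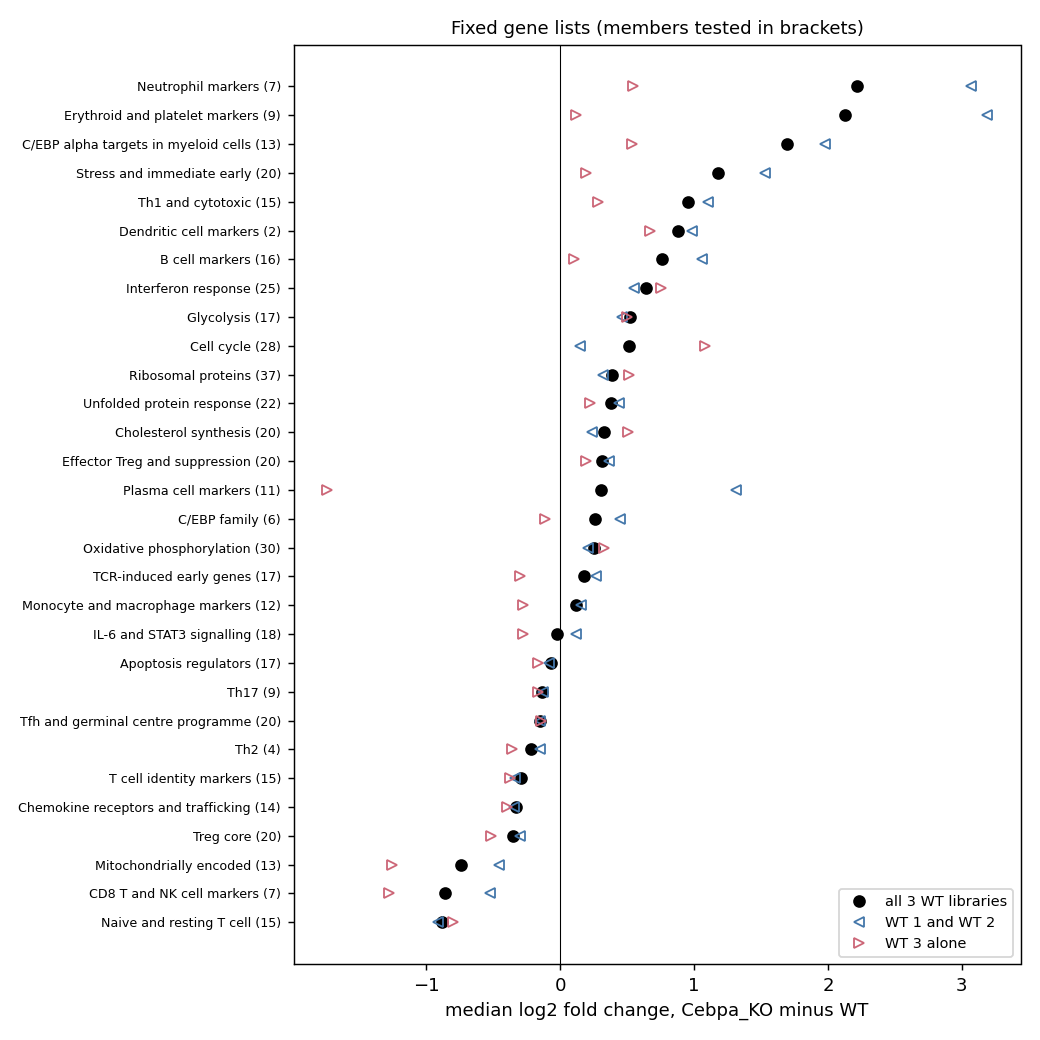
Median log2 fold change of 30 gene lists, Cebpa_KO minus WT, with filled points for all 3 WT libraries and open triangles for WT replicates 1 and 2 or WT replicate 3 alone. The interferon list lies at 0.64, 0.55 and 0.75 in these settings, whereas the stress list lies at 1.18, 1.53 and 0.19.

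Of 29 lists with at least 5 tested members, 10 were higher and 7 lower by camera with a preset correlation, and 0 passed with an estimated one, where adjusted p lay between 0.60 and 0.991. The 6 lists past fry were the Treg core, naive and resting, trafficking, T cell identity, glycolysis and sex-linked ones. The interferon and ribosomal protein lists did not pass by fry (adjusted p = 0.0582 and 0.0656). Counts of single genes in lists were lower without WT replicate 2, such as 3 rises in glycolysis, 4 in ribosomal proteins, 0 in cholesterol synthesis and 3 falls in the Treg core, and no list but the sex-linked one kept more than 2 calls without a Cebpa_KO library. With WT replicate 3 as the only WT library the camera calls of the stress, unfolded protein response and neutrophil lists ended too, at 0.145, 0.271 and 0.865. In that setting all spread comes from the 2 Cebpa_KO libraries. Sex, the Foxp3 allele and the Cebpa deletion separated the same libraries, so no value here is assigned to the deletion alone.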

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

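All tests of explanations in this part were chosen after the results were seen. At 22 places, loci without an annotated row were assembled in both Cebpa_KO libraries at 5 TPM or more and in no WT library. These rows of the deposited tables are a signal that the comparison did not use. The reverse held at 7 places, but asked for 5 TPM in all 3 WT libraries and absence from 2. The counts are therefore not a like comparison. The highest of the 22 were on chromosome 1 from 164055667, with a mean of 27.7 TPM, and on chromosome 12 from 19293889, with a mean of 26.5 TPM. Others lay on chromosome Y, from 42994951 at 33.7 and 15.9 TPM and from 90745677 at 6.25 and 17.6 TPM in Cebpa_KO replicates 1 and 2. Eif2s3y, Ddx3y, Uty and Kdm5d summed to 0 and 0.0311 in these libraries. This argues against the Y chromosome as the source of the reads placed on it. The reads at the 22 places were not matched to sequence, so copies elsewhere in the genome were not ruled out. Absence from an assembly does not mean that no reads were there.

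Foxp3 was 16.0 times lower in Cebpa_KO, in cells sorted for it. Reads that the annotated row leaves out do not account for this, since the assembled Foxp3 locus was also lower, by a ratio of 18.5. Dilution by cells without the regulatory T cell genes would lower the others alike. But the other 19 core genes had a median of -0.33 and a lower quartile of -0.57 against -3.79 for Foxp3. This argues only against cells that lack these genes as a set. Dilution by cells without Foxp3 that express many of the other core genes was not tested. The sex of the mice cannot be told apart from the genotype, since Eif2s3y, Ddx3y, Uty and Kdm5d followed the label in 5 of 5 libraries. The Foxp3 allele, a reporter in WT and a Cre in Cebpa_KO, and the loss of Cebpa are further open explanations and were not tested apart.

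Heat shock and immediate early transcripts were high in WT replicate 3 as in both Cebpa_KO libraries. A wrong label of WT replicate 3 is argued against by Cebpa, which was 23.2 times the higher Cebpa_KO value there. Handling alike in WT replicate 3 and both Cebpa_KO libraries does not account for the calls as a whole, since WT replicates 1 and 2 against these 3 libraries gave 48 genes, against 3210 by genotype. Handling that differed in strength between WT replicate 3 and Cebpa_KO is not excluded by this. The genotype difference adds to the spread within that split, so the 48 is not a count of genes that handling changed. What raised the stress transcripts themselves was not tested, handling included, since no label records it. No biological explanation was tested either, since no label separates WT replicate 3.

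Ighg1 was at 288 and 111 in Cebpa_KO and at 3.09 or less in WT. More RNA of antibody-secreting cells would raise their other transcripts alike, but the other plasma cell markers had a median log2 fold change of 0.29 and an upper quartile of 0.38 against 6.62. These depended on WT replicate 3, but the gap did not: against WT replicates 1 and 2 the other markers had a median of 1.10 and an upper quartile of 1.61 against 7.19, and against WT replicate 3 a median of -1.77 and an upper quartile of -1.18 against 5.46. More such RNA than in WT replicates 1 and 2 is thus not excluded, only as the whole of the Ighg1 difference. Jchain and Ighg2c were highest in WT replicate 3, at 456 and 2481, where Ighg1 was at 3.09. Ighg1 made up 13.6% and 15.2% of the IgG heavy chain transcripts in Cebpa_KO and at most 0.170% in WT. A different IgG class makeup between these mice remains a hypothesis, and strain variants of the heavy chain locus were not tested.

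The count of 3210 changed genes was set against the other splits of the 5 libraries into 3 and 2, of which 1 of 10, the real one, reached it. The highest other split, WT replicates 1 and 2 against the rest, gave 48 genes. Every other split mixes the genotypes within a group, so the genotype difference adds to the spread and lowers the count. The other counts are therefore not what a comparison without any difference would give. The 10 splits are too few for a share under 0.05.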

How the results depend on the processing

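Settings chosen after seeing the data are WT replicate 3 alone, the assembled loci and the counts without chromosomes X and Y. Against 1614 genes higher and 1596 lower, no filter gave 930 and 629 and array weights 2575 and 2440, and WT replicate 3 alone gave 1014 and 647. In that fit all spread comes from the 2 Cebpa_KO libraries. The assembled loci gave 1100 higher, 1052 lower and 15 lists. Leaving out 1 library gave 5 to 2177 higher and 18 to 1825 lower, with a lone Cebpa_KO library assumed to vary like the WT. The lists past the threshold, 17, were 13 to 20 with 1 library left out, 10 with WT replicate 3 alone, 6 by fry and 0 with an estimated correlation. Calls were lost with no filter, where more genes were tested, and when a library other than WT replicate 3 was left out. Leaving out WT replicate 3 gave 2177 higher and 1825 lower, so the number of samples alone did not set the count. The causes were not tested. Cebpa was -4.79 with a pseudocount of 0.1 and -1.83 with 5, ranged from -3.54 to -3.27 with 1 library left out, and it fell below the filter with WT replicate 3 alone.

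The replicate block gave 1359 higher and 1050 lower. With it the plasma cell, erythroid, myeloid target and effector Treg lists passed by camera, at adjusted p of 8.22e-05, 0.00212, 0.0141 and 0.0313, and the cell cycle, cholesterol and CD8 T and NK cell lists did not, at 0.061, 0.0688 and 0.0554. Only 2 numbers are shared and the labels do not say that they pair libraries, so the numbers are not taken as pairs. Deviations of same-numbered libraries correlated across genes at -0.179 and 0.269. Deviations of the 2 Cebpa_KO libraries from their mean mirror each other, so these values cannot decide on pairing. Trac and Cd22 did not pass with the block, at adjusted p of 0.0997 and 0.0602. Named genes that had passed and no longer did numbered 40 with no filter, at most 5 with no trend, quantile normalization or unscaled TPM, 19, 46 and 3 without WT replicates 1, 2 and 3, 29 with WT replicate 3 alone, 15 in the assembled loci and 13 with the block. Prdm1, not past the threshold, was 0.014 with the replicate block and -0.23 to 0.022 with 1 library left out. With WT replicate 3 alone Cebpb, Txndc5, Ighg2b and Ighg2c changed sign, to -0.48, -0.13, -1.99 and -1.55. With the assembled loci Isg20, Fasl, Tpi1, H2-Aa, Ighg2c and Klrb1c changed sign, to -3.35, 0.38, -1.13, -2.46, -1.95 and 0.071, and the cause was not tested. The other named genes kept their direction in every setting that gave a value. Depth was alike across libraries, and the files give no counts from which a limit for low genes could be set.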

Other observations

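The genes, list and tests in this part were chosen after values had been seen. Ribosome assembly factors were higher in Cebpa_KO: Nop56, a core protein of small nucleolar particles, went from 193.0 ± 20.1 to 411.8 ± 2.58 (n = 3 and 2), Npm1, nucleophosmin, from 265.7 ± 11.3 to 590.4 ± 107 and Ncl, nucleolin, from 137.9 ± 2.91 to 276.8 ± 22.7. Vdr, the vitamin D receptor, rose from 2.33 ± 0.486 to 20.5 ± 1.39, and Kit, the stem cell factor receptor, from 0.784 ± 0.383 to 6.43 ± 0.156. Atp1b1, a beta subunit of the sodium pump, fell from 37.6 ± 3.60 to 5.65 ± 0.501, and Atp6v0d2, a proton pump subunit, from 19.9 ± 1.08 to 1.05 ± 0.139. Cd55, a complement regulator, fell from 43.0 ± 4.23 to 6.08 ± 2.54.

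A hypothesis from the first of these was that ribosome biogenesis as a whole is raised in Cebpa_KO. In a list of 34 such genes, written without those seen first, 29 rose and none fell, with a median log2 fold change of 0.89. The median was 0.95 against WT replicates 1 and 2 and 0.72 against WT replicate 3. The list passed camera with a preset correlation (p = 6.25e-16, limma) but not with an estimated one (p = 0.107), so the test leaves open whether these genes may stand apart from the rest.

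Cd22 and Hpn were lower and lie near Cebpa on chromosome 7, so a linked stretch carried with the floxed allele was tested as a possible explanation. Of 282 genes within 10 Mb of Cebpa, 5.32% changed by at least 2-fold, against 4.72% elsewhere. Cebpg, which lies nearer to Cebpa than Cd22 does, rose by 0.76 on the log2 scale and was under that bound. The odds ratio was 1.13 (95% confidence interval 0.623 to 1.92, Fisher's exact test, p = 0.573), which gives no excess of changed genes there; single linked variants were not tested.

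Without chromosomes X and Y, 1565 genes were higher and 1553 lower, against 1614 and 1596 over all chromosomes. Flicr, a non-coding RNA beside Foxp3, fell from 11.5 to 1.71.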
